A study of Mus musculus with 21 samples.

How the data were processed

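RNA-seq of male germ cells sorted by Oct4-GFP from matings of Tex15 heterozygotes was analysed in 21 libraries, 3 biological replicates for each of 7 groups: heterozygous (HT) and knockout (KO) cells at E16.5, E18.5 and D2.5, and wild type (WT) at D2.5. Per the labels, total RNA was taken with a PicoPure kit, amplified with NuGEN Ovation kits and sequenced on a HiSeq 4000. The submitters' notes name STAR, Bowtie, featureCounts, edgeR and the mm9 genome; versions and the role of each are not given in the sources used here. The deposited values are counts: 3 tables hold read counts for 24495 gene rows and 1217 repeat names. The authors' other 3 tables hold alignment counts for 53 repeat families. Family totals were 250719898 to 1254023075 per library, far above the read counts, so a read can count many times. Yet the Satellite family in HT at E18.5 (8500 CPM) held less than its member GSAT_MM alone in the read counts. Family and name counts are thus not on the same scale. The values are whole numbers in both kinds of table.

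Table totals were 16661750 to 23353300 counts per library and gene totals 6063632 to 11884109, lowest at D2.5 (6063632 to 7391401). Repeat names took 41.9% to 69.4% of the counts, and 2359 to 8279 genes per library were at 0. A count of 3 corresponds to 0.259 to 0.49 CPM. The biological coefficient of variation was 37.3% at E16.5, 17.9% at E18.5 and 55.4% at D2.5. Tested on simulated data with 200 changed genes, edgeR recovered 42.4% of 4-fold changes at E16.5, 89.4% at E18.5 and 50% at D2.5. In the E16.5 simulation 81 of 196 DESeq2 calls were false, against 4 of 86 in edgeR and 1 of 78 in limma-voom. Each gene was drawn independently, so variation that genes share between real libraries is left out of these values.

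Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group (minimum count 10, minimum total 15), TMM factors, quasi-likelihood fits and two-sided tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. E16.5 and E18.5 were fitted alone (6 libraries each), D2.5 with all 9 libraries. Differences of the KO effect between ages and changes with age in HT were contrasts of 1 fit of the 18 HT and KO libraries. Repeat families and names with at least 10 reads in at least 3 libraries were tested in the same way, with library sizes and TMM factors of the genes. At E18.5 and D2.5 their estimated prior degrees of freedom were infinite (10.9 for families and 3.51 for names at E16.5). Each family or name there took the spread of rows of like abundance, so its SE and p do not measure its own replicate spread. Repeat names and family differences between ages were added after seeing the data. The 20 gene lists (14 to 30 genes, 426 in all, 15 in more than 1 list) cover the piRNA pathway, DNA methylation machinery, H3K9 and KRAB repression, methylation-sensitive germline genes, fetal and pluripotency genes, undifferentiated and differentiating spermatogonia, meiotic prophase, spermatid, interferon, p53, imprinted, MERVL-linked, cell cycle and stress genes, and markers of Sertoli, Leydig, stromal, endothelial and macrophage cells. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, again with an estimated correlation and with fry; the MERVL-linked list had fewer tested genes at E16.5 and D2.5. DESeq2 1.42.0 and limma-voom were the other gene tests, and figures used Python 3.11.15 with matplotlib 3.10.9.

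Groups, comparisons, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule took Tex15, then per direction the 10 genes with the largest log2 fold change among those that passed with an average log2 CPM of at least 1 and no overlap between groups (5 for the other comparisons), and up to 4 passing or 2 other members of each list; predicted gene models were counted and not named. Genes outside it, such as the further members of chemosensory families and the D2.5 genes followed back to E18.5, were chosen after their values were seen. Alternatives were other scaling factors, no filter or a stricter one, DESeq2, limma-voom, replicate blocks and leaving out each library; TMM over genes and repeats, GC-corrected offsets, library weights, a covariate and the newer quasi-likelihood method were added after seeing the data. Random lists (10000) matched genes in 20 expression bins. For a group with no counts, 3 counts per library set the limit. A GRCm38 annotation served for gene neighbours, GC content and repeated 31-mers, and 24124 gene rows (98.5%) matched it by name. Reads were not realigned here.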

Results

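Oct4-GFP sorted male germ cells lacking Tex15 (KO) were compared with heterozygous cells (HT) at embryonic days 16.5 and 18.5 (E16.5, E18.5) and after birth, where wild-type cells (WT) were profiled too. The postnatal age is 2.5 days in the sample labels (D2.5) and day 2 in the design text of the series. Each of the 7 groups held 3 libraries. Values are gene counts scaled to library size (CPM) and log2 fold changes with their standard error (SE). The comparison asks which genes and repeated elements are expressed differently when Tex15 is missing.

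Tex15, which has a known role in meiotic recombination in male germ cells, was lower in each KO library than in each control library of its age. HT cells held a mean Tex15 level of 987 CPM at E16.5 (SD 98.2, n = 3), 958 CPM at E18.5 (SD 44.3, n = 3) and 1640 CPM at D2.5 (SD 177, n = 3). KO cells held 3.45 CPM (SD 0.475, n = 3), 3.71 CPM (SD 0.272, n = 3) and 18.1 CPM (SD 3.53, n = 3). By edgeR the log2 fold change of Tex15 was -8.16 at E16.5 (SE 0.20, adjusted p = 2.26e-05), -8.01 at E18.5 (SE 0.19, adjusted p = 3.44e-12) and -6.49 at D2.5 (SE 0.18, adjusted p = 4.6e-17). WT cells at D2.5 held 3510 CPM (SD 343, n = 3). The HT against WT log2 fold change was -1.10 (SE 0.14, edgeR adjusted p = 0.00133) and that of KO against WT -7.60 (SE 0.19, edgeR adjusted p = 3.97e-18). Between 30 and 131 Tex15 counts remained in each KO library. A count per gene does not show which part of the transcript they cover.

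**Figure D1:**
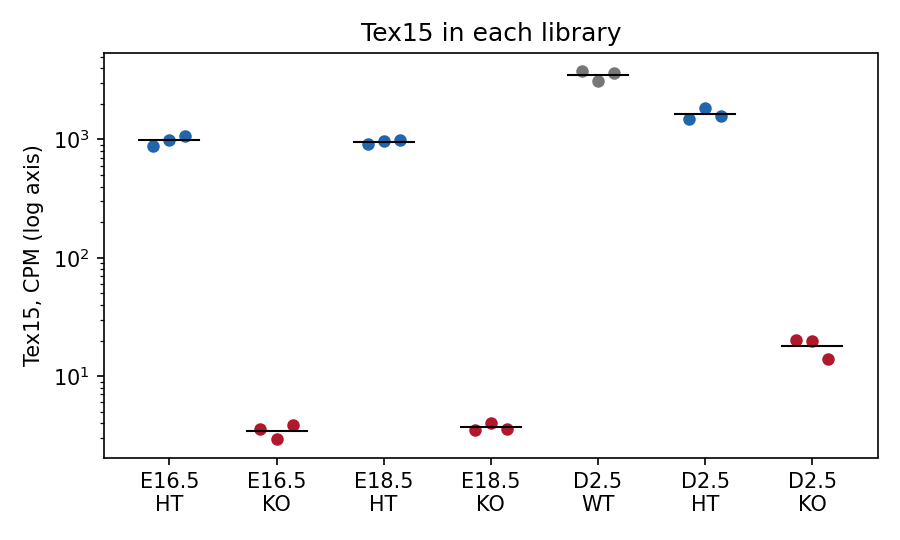
Tex15 expression in CPM (log axis) in each of the 21 libraries by age and genotype; points are libraries and lines are group means. The KO means lie at 3.45, 3.71 and 18.1 CPM and the HT means at 987, 958 and 1640 CPM.

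At E16.5, families of endogenous retroviruses were already higher in KO cells. ERVK, the family of the intracisternal A particles (IAP) and other mobile mouse retroviruses, rose by a log2 fold change of 1.15 (SE 0.20, n = 3 per group, edgeR adjusted p = 0.00176), and ERV1, which holds elements of the murine leukaemia virus type, by 0.82 (SE 0.18, edgeR adjusted p = 0.00629). The families named NA (0.65, SE 0.14) and RNA (0.72, SE 0.17) rose as well, so that 4 of the 52 families tested passed. L1, the main mobile LINE family, had a log2 fold change of 0.46 (SE 0.29, edgeR adjusted p = 0.596). Each KO library lay above each HT library for L1 (25100000 to 42700000 CPM against 21700000 to 23200000 CPM). The KO libraries were spread, with 430165720 L1 counts in KO replicate 3 and 297622320 and 291137985 in KO replicates 1 and 2. ERVL was at 0.23, and the SINE families Alu, B2 and B4 were at -0.12, -0.06 and 0.01. The strongest single repeat names belonged to IAP: IAPLTR1_Mm had a log2 fold change of 1.34 (SE 0.19) and IAPEz-int of 1.17 (SE 0.17), each with an adjusted p of 0.0857 in edgeR. Of 1090 repeat names 0 passed in edgeR and limma-voom and 2 in DESeq2, and 67 had an unadjusted p under 0.05 in edgeR. More names passed with the replicate number as a block. With the totals of the family tables as library sizes, of which L1 makes up most, ERVK (0.69) passed while ERV1 (0.34), NA (0.19) and RNA (0.28) did not. L1 was then at -0.03 and ERVL at -0.22. Without KO replicate 2, ERV1 (0.90) and RNA (0.65) no longer passed.

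Among 16185 genes tested at E16.5, Tex15 alone passed in edgeR, and 190 genes had an unadjusted p under 0.05. That is 1.17% of the genes, fewer than chance alone gives on average. The count is thus no sign of further changes, and the fit may be too cautious at this age. A fit with the replicate number as a block called 2 genes, and 874 had an unadjusted p under 0.05. Limma-voom called 1 gene and DESeq2 6. Libraries differed more than genotypes at this age. HT replicate 1 stood apart from the other libraries (-127.3 on the first principal component, which held 78.2% of the variance; KO replicate 3, on the opposite side, was at 74.8). In it Dppa3, an early germ cell gene, was 2.55 higher on the log2 scale and the proliferation gene Mki67 2.21 higher than the mean of the other HT libraries. The Mki67 mean was 225 CPM in HT (SD 210, n = 3) and 73.7 CPM in KO (SD 7.69, n = 3), with a log2 fold change of -1.61 (SE 0.62, edgeR adjusted p = 0.976).

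The gene lists at E16.5 moved with that library. All 27 cell cycle genes tested had a lower fitted value in KO (median log2 fold change -0.37, camera adjusted p = 6.76e-07; adjusted p = 0.825 with an estimated correlation). Of 21 fetal germ cell and pluripotency genes 19 were below 0 (median -1.02, camera adjusted p = 0.000952; adjusted p = 0.825 with an estimated correlation), with Lefty1 at -3.41 and Lefty2 at -2.40, both targets of Nodal signalling. Of 9 macrophage and blood markers tested 8 were above 0 (median 0.52, camera adjusted p = 0.0388; adjusted p = 0.825 with an estimated correlation), with the mannose receptor Mrc1 at 1.87. No single member of these lists passed, over all genes or adjusted over the list alone. Without E16.5 HT replicate 1 in KO vs HT at E16.5, camera's adjusted p was 0.232, 0.293 and 0.658 for the 3 lists in that order. The fetal list was also at 0.264 without KO replicate 3, and the macrophage list at 0.057 and 0.138 without KO replicates 2 and 3. Over all alternatives the adjusted p ranged from 1.49e-09 to 0.89, from 1.07e-08 to 0.89 and from 0.0122 to 0.89. The other lists had camera adjusted p of 0.0539 (piRNA pathway, median 0.16), 0.0675 (H3K9 and KRAB repression, -0.21), 0.132 (spermatid) and 0.167 (endothelial markers) or more. Median, mean and test differed in sign for the methylation-sensitive germline, meiotic, interferon and imprinted lists.

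At E18.5, L1 and the long terminal repeat families ERV1 and ERVK were higher in KO cells relative to gene counts. The edgeR p of families and names at E18.5 and D2.5 rest on a spread shared between rows, not on each row's own. ERV1 rose by a log2 fold change of 1.77 (SE 0.16, n = 3 per group, edgeR adjusted p = 5.48e-21), L1 by 1.87 (SE 0.19, edgeR adjusted p = 5.26e-18) and ERVK by 1.59 (SE 0.17, edgeR adjusted p = 2.06e-16). The NA family rose by 1.18 (SE 0.16), and Satellite fell by 0.47 (SE 0.15, edgeR adjusted p = 0.0199), a call that ended without HT replicate 3 (-0.43), KO replicate 1 (-0.45) or KO replicate 2 (-0.41). ERVL (0.29), MaLR (0.27), Alu (0.07), B2 (0.08) and B4 (0.09) did not pass. With the family totals as library sizes, of which L1 makes up most, L1 was at 0.07, ERV1 at -0.01, ERVK at -0.18, NA at -0.61, ERVL at -1.50 and Alu, B2 and B4 at -1.71, -1.69 and -1.70.

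**Figure D2:**
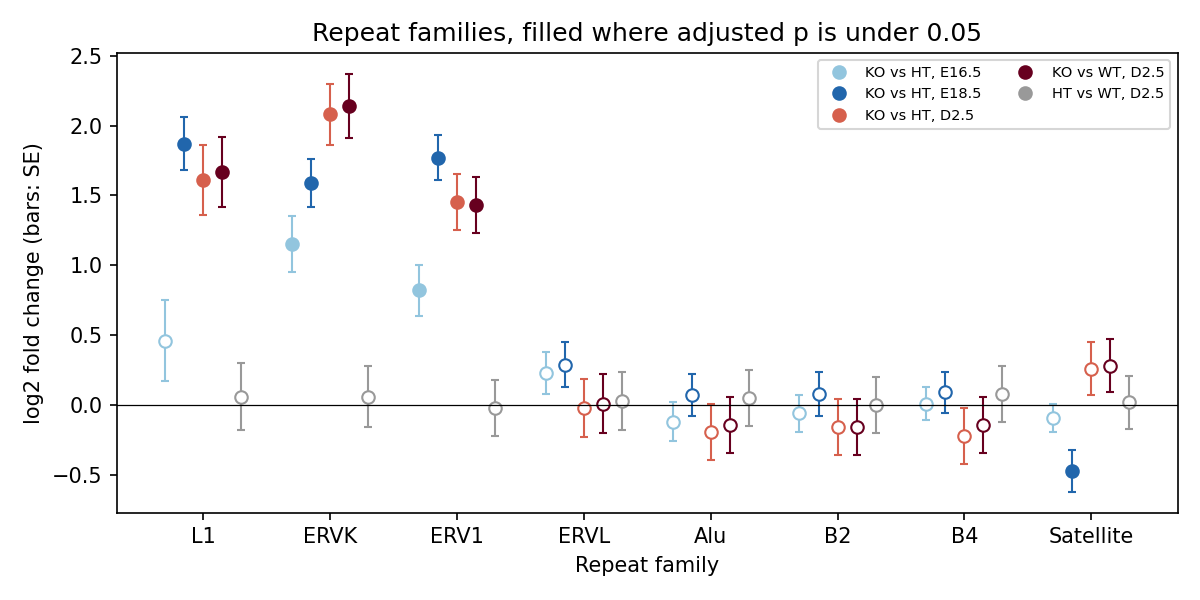
Log2 fold change (with SE bars) of 8 repeat families in 5 comparisons, scaled to gene counts; filled points passed at an adjusted p under 0.05 in edgeR. L1, ERV1 and ERVK are at 1.87, 1.77 and 1.59 in KO vs HT at E18.5 and at 1.61, 1.45 and 2.08 at D2.5. With family totals, which are mostly L1, as library sizes ERV1 is at -0.01 and -0.07 and ERVK at -0.18 and 0.58.

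Many single repeat names were higher in KO at E18.5. Of 1125 names 113 passed in edgeR, 111 of them higher in KO. All 6 young mouse L1 names passed (median 1.22), with L1Md_A at 1.65 (SE 0.19, edgeR adjusted p = 1.4e-15) and 10700 CPM in KO against 3420 CPM in HT. All 16 IAP names passed (median 1.13), led by IAPLTR4_I at 2.86 (SE 0.20, edgeR adjusted p = 7.72e-43), with IAPEz-int at 1.47. So did all 5 ETn and MusD names (median 0.96, ETnERV-int 1.54), all 9 murine leukaemia virus type and VL30 names (median 1.31, MuRRS-int 1.78) and 8 of 9 MMERVK10C and RLTR10 names (median 1.11). In other groups 18 of 28 other rodent L1 names passed (median 0.54), 0 of 75 ancient L1 names in edgeR (median 0.12), 1 of 97 MaLR names (0.22), 1 of 3 MERVL names (0.35) and 0 of 27 rodent SINE names in edgeR (0.08), beside a median of 0.18 for all names. The major satellite GSAT_MM went the other way, from 18400 CPM in HT (SD 478, n = 3) to 2790 CPM in KO (SD 935, n = 3), a log2 fold change of -2.73 (SE 0.20, edgeR adjusted p = 1.05e-37), and SYNREP_MM fell by 1.05. With the totals of the repeat names as library sizes all names moved by a median of -0.29 and 0 of the 113 changed sign (L1Md_A 1.35, IAPEz-int 1.18, GSAT_MM -3.03), but the calls then numbered 94, 76 higher and 18 lower, and 78 of them were among the 113. Of the 113 calls, 58 held without any 1 library. Among other rodent L1 names L1VL1 (0.89) alone did so. With the totals of the repeat names as library sizes some of these names, such as Lx (0.26), missed the threshold, while others, such as L1_Mm (0.43), passed. The calls of L1Md_T (0.59) and MERVL-int (0.49) each ended without HT replicate 3, KO replicate 1 or KO replicate 3, among others. The number of all names called was 63 to 65 without HT replicate 3, KO replicate 1 or KO replicate 3 and 274 without HT replicate 1.

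**Figure D3:**
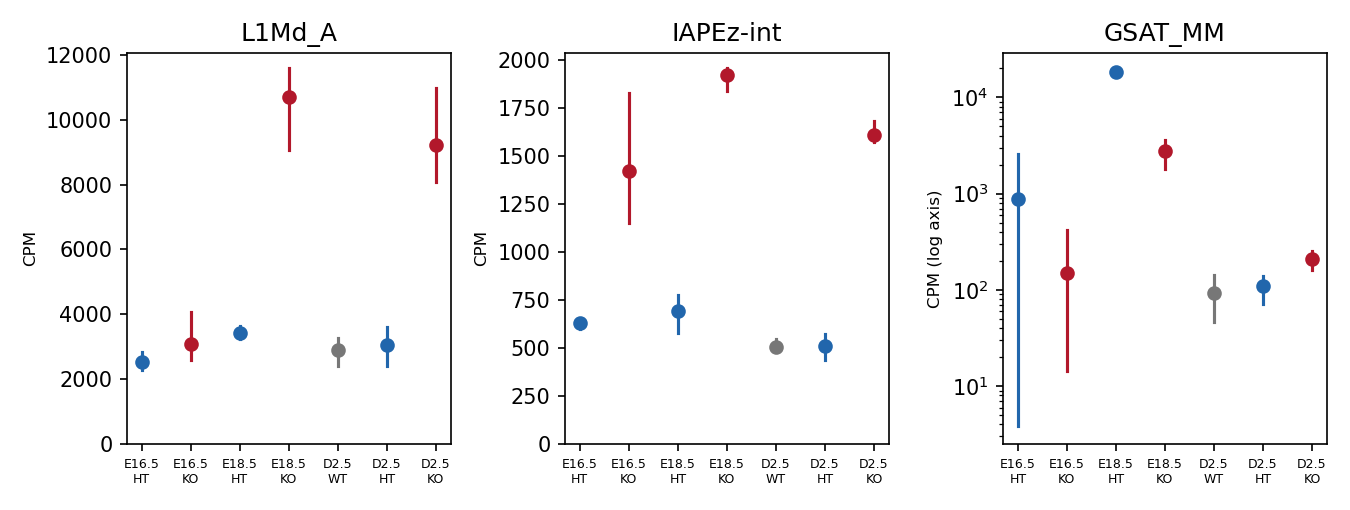
CPM of L1Md_A, IAPEz-int and GSAT_MM (log axis for GSAT_MM) by age and genotype; points are means of 3 libraries and bars run from the lowest to the highest library. L1Md_A is at 3420 CPM in HT and 10700 CPM in KO at E18.5, and at 3060 and 9220 CPM at D2.5; GSAT_MM is at 18400 and 2790 CPM at E18.5.

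Genes at E18.5 changed almost only upward in KO cells. Of 18199 genes tested 389 passed in edgeR, 377 higher and 12 lower, with a median log2 fold change of 1.83 among the higher ones. The higher genes included chemosensory receptors hardly detected in HT cells: Olfr11 went from 0.397 to 17.7 CPM (SD 1.65 in KO, n = 3; log2 fold change 5.38, SE 0.38, edgeR adjusted p = 3.56e-06), Olfr293 had a log2 fold change of 4.77 (SE 0.43), Vmn1r14 of 4.58 (SE 0.52) and Olfr419 of 5.05 (SE 0.65). Adam39 (4.41, SE 0.57) and Speer2 (3.76, SE 0.49), relatives of testis genes, rose too. HT counts of these genes were few, and leaving out 1 HT library moved the fold by more than 1.5 times: Olfr11 KO vs HT at E18.5 was 6.31 and Vmn1r14 KO vs HT at E18.5 was 5.33 without HT replicate 3. Without HT replicate 2, Olfr293 KO vs HT at E18.5 was 5.61 and Adam39 KO vs HT at E18.5 was 5.22, and Olfr419 had no HT counts left. Reads of such gene families can be shared between near-identical copies, so the copy of origin is uncertain. Of the 11 name prefixes counted, all chosen after seeing the calls, 36 of 120 Olfr genes tested, 24 of 57 Vmn, 10 of 77 Cyp, 4 of 38 Serpin, 2 of 8 Akr1c, 2 of 9 Gbp, 2 of 13 Ifi and Sp100 type, 2 of 23 Cdh, 11 of 377 Slc, 0 of 9 Slfn (in edgeR) and 1 of 358 Zfp genes were among the 377. The genes tested were picked by a filter that also lets in genes expressed in KO alone, so these counts have no fair chance value. Of the 377 genes, 114 had a mean under 1 CPM in HT, and the median HT level of all 377 was 2.64 CPM against 15.7 CPM for all genes tested.

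**Figure D4:**
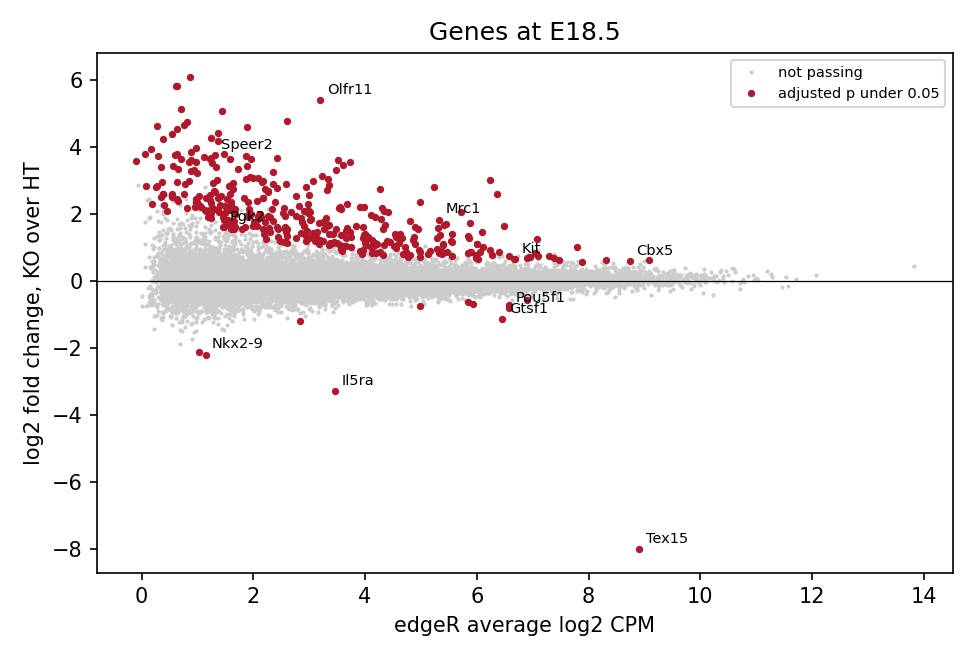
Log2 fold change of KO vs HT at E18.5 against average log2 CPM for the genes tested; coloured points passed in edgeR, and labelled genes are named in the text. Of the 389 genes that passed, 377 lie above 0.

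The 12 lower genes included the germ cell genes Gtsf1 and Pou5f1. Il5ra, the interleukin 5 receptor chain, went from 19.7 CPM (SD 6.67, n = 3) to 1.98 CPM (SD 0.391, n = 3; log2 fold change -3.29, SE 0.30, edgeR adjusted p = 3.78e-05). Gtsf1, a piRNA pathway protein, went from 121 CPM (SD 11, n = 3) to 54.5 CPM (SD 6.33, n = 3; -1.15, SE 0.15, edgeR adjusted p = 0.000554). Pou5f1, which encodes Oct4, the factor behind the sorting reporter, fell from 121 to 69.1 CPM (-0.81, SE 0.18, edgeR adjusted p = 0.0307), and so did Nkx2-9 (-2.21), Akr1b7 (-1.20), Zmat4 (-0.76), the cohesin acetyltransferase Esco2 (-0.74) and Fbxo15 (-0.71). The call of Pou5f1 ended without HT replicate 2 (-0.73), HT replicate 3 (-0.83), KO replicate 1 (-0.66) or KO replicate 3 (-0.77). That of Nkx2-9 KO vs HT at E18.5 ended without HT replicate 2, HT replicate 3 or KO replicate 3 (-1.99 to -2.28). Akr1b7 KO vs HT at E18.5 missed the threshold without HT replicate 1, 2 or 3 or KO replicate 1 or 2 (-1.05 to -1.28), Zmat4 without HT replicate 2 or 3 or KO replicate 1 or 3 (-0.65 to -0.78), Esco2 without any 1 library other than KO replicate 2 (-0.56 to -0.80), and Fbxo15 without HT replicate 1, 2 or 3 or KO replicate 3 (-0.59 to -0.76). Of all genes, 197 were called without HT replicate 2, 251 without HT replicate 3 and 237 without KO replicate 3.

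Of the 20 gene lists, 0 passed camera at E18.5, and 4 had an unadjusted p under 0.05. The lowest adjusted p was 0.0984, for meiotic prophase (median -0.12). The piRNA pathway list had 1 of 23 genes lower, Gtsf1, and a median of 0.03; the DNA methylation machinery 0 of 12 in edgeR (0.03). H3K9 and KRAB repression had 1 of 19 higher (0.02), the heterochromatin protein Cbx5, from 341 to 515 CPM (0.60, SE 0.15, edgeR adjusted p = 0.049). The methylation-sensitive germline genes had 1 of 23 lower, Tex15 itself (median -0.11), and the MERVL-linked genes 0 of 8 in edgeR (0.26; 1 higher adjusted over the list alone). Kit, the receptor of differentiating spermatogonia, rose from 80.3 to 126 CPM (0.65, SE 0.14, edgeR adjusted p = 0.0201), and the spermatid list had Pgk2 at 1.60. Of 27 interferon-stimulated genes 2 rose, Ifi44 (1.14) and Samd9l (1.12), with a list median of -0.10. Medians were -0.17 for fetal and pluripotency genes, -0.07 for undifferentiated and -0.07 for differentiating spermatogonia, 0 for spermatid, -0.02 for p53, -0.04 for imprinted, -0.09 for cell cycle and 0.07 for stress genes.

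Markers of other testis cell types held a median log2 fold change of -0.014 at E18.5 over 74 genes, of which 3 rose: Mrc1 from 17.7 CPM (SD 3.44, n = 3) to 62.5 CPM (SD 5.56, n = 3; 1.82, SE 0.18, edgeR adjusted p = 6.27e-05), Adgre1 (1.43) and the endothelial receptor Tek (0.87). List medians were -0.05 for Sertoli, 0.04 for Leydig, 0.04 for stromal, -0.02 for endothelial and 0.29 for macrophage markers (camera adjusted p = 0.134 for the last; adjusted p = 0.921 with an estimated correlation for each list). Several list members lay near the threshold. Cbx5 missed the threshold without any 1 of the 6 libraries (0.49 to 0.65), with RLE factors (0.59) or with GC-corrected offsets (0.46). Kit missed it without HT replicate 1, 2 or 3 or KO replicate 2 or 3 (0.61 to 0.67) and Pgk2 without any library other than KO replicate 2 (1.39 to 1.78) or with limma-voom (1.55). Ifi44 missed it without HT replicate 1 or 2 or KO replicate 3 (0.95 to 1.08), Samd9l without HT replicate 2 or 3 or KO replicate 2 or 3 (0.97 to 1.10), and Adgre1 (1.28 to 1.46) and Tek (0.76 to 0.85) without HT replicate 2, HT replicate 3 or KO replicate 3. With 1 library left out of KO vs HT at E18.5 some lists passed camera: cell cycle without KO replicate 2 (adjusted p = 0.0497), macrophage without KO replicate 1 (0.0201), meiotic prophase without HT replicate 3 (0.0362) or KO replicate 3 (0.0293) and methylation-sensitive germline genes without KO replicate 2 (0.0246). Median, mean and test differed in sign for the piRNA, differentiating spermatogonia, spermatid, interferon, p53 and stress lists.

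At D2.5, ERVK, ERV1 and L1 were again higher in KO than in HT cells. ERVK rose by a log2 fold change of 2.08 (SE 0.22, n = 3 per group, edgeR adjusted p = 1.8e-16), L1 by 1.61 (SE 0.25, edgeR adjusted p = 3.69e-09) and ERV1 by 1.45 (SE 0.20, edgeR adjusted p = 1.17e-10), where family totals as library sizes put ERVK at 0.58, L1 at 0.07 and ERV1 at -0.07. The RNA family rose by 0.76 (SE 0.21; -0.74 with family totals), a call that ended without HT replicate 1 (0.65) or KO replicate 3 (0.59). ERVL had a log2 fold change of -0.02 and Alu of -0.19. Of 1110 repeat names 14 passed, 13 of them higher: L1Md_A, at 9220 CPM in KO against 3060 CPM in HT, had a log2 fold change of 1.59 (SE 0.22, edgeR adjusted p = 2.1e-10), IAPEz-int of 1.65 (SE 0.22) and IAPLTR1_Mm of 2.35 (SE 0.28, edgeR adjusted p = 3.05e-14), while L1Md_T was at 0.02. GSAT_MM was higher here (0.92, SE 0.26, edgeR adjusted p = 0.0397), a call that ended without HT replicate 1, HT replicate 3 or KO replicate 2 and with the totals of the repeat names as library sizes (1.05, edgeR adjusted p = 0.127). Young L1 held 2 of 6 passing names, IAP 4 of 16, MLV and VL30 types 2 of 9 and ETn and MusD 0 of 5 in edgeR, beside a median of -0.18 for all names. With the totals of the repeat names as library sizes all names moved by 0.15 and 0 of the 14 changed sign, while 36 names passed, all higher, 12 of them among the 14. Of the 14 calls, 9 held without any 1 library. Another split of these HT and KO libraries, HT replicate 1 with KO replicates 1 and 2 against the rest, called 352 names.

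Fewer single genes passed at D2.5 than at E18.5: 22 of 14367 in edgeR, 21 of them higher and Tex15 lower. More genes were called higher than lower in each method, but the balance varied. DESeq2 called 82 higher and 44 lower, edgeR without a filter 83 and 26, and limma-voom 24 and 1. In edgeR 1036 genes had an unadjusted p under 0.05. Samd9l, an interferon-stimulated gene, was at 0.803 CPM in HT (SD 0.519, n = 3) and 100 CPM in KO (SD 22.4, n = 3; log2 fold change 6.91, SE 0.60, edgeR adjusted p = 4.28e-07). The cadherins Cdh19 (7.71, SE 0.76) and Cdh12, at 13.3 CPM in HT and 233 CPM in KO (4.12, SE 0.36), rose too. So did the receptor Gpr179, from 0.185 to 65.9 CPM (8.28, SE 0.74), complement C6 (5.99, SE 0.73) and the taste transducin Gnat3 (4.37, SE 0.62). Low HT counts moved several folds: Gpr179 KO vs HT at D2.5 was 9.43 and Samd9l KO vs HT at D2.5 was 7.50 without HT replicate 2, C6 KO vs HT at D2.5 was 7 and Gnat3 KO vs HT at D2.5 was 6.05 without HT replicate 3, and Slc15a2 was 7.08 and Cyp7b1 KO vs HT at D2.5 was 6.15 without HT replicate 1. Asb12 had no counts in HT and was at least 26.2-fold higher in KO, taking 3 counts per library as the limit. Cyp4a12b, whose reads may be shared with its near-identical copies, had 2 HT counts and a ratio of 287 (counting interval 79.2 to 2380). Of the 22 genes 14 were also among those higher at E18.5, Gpr179 at 2.60, Cdh19 at 3.25 and Cdh12 at 1.66 there. Calls unrelated between the ages would give 0.271 such genes on average. Genes that vary together are not independent, so no p is given for this overlap. The call of Slc15a2 KO vs HT at D2.5 (5.12) ended without HT replicate 2 (4.77), KO replicate 1 (5.04) or KO replicate 2 (5.13). The call of Cyp7b1 (5.51) ended without HT replicate 2 (5.12), HT replicate 3 (5.42) or KO replicate 3 (4.90). Those of Cyp7b1, Asb12 and Cyp4a12b ended with limma-voom, and Asb12 also missed the threshold without HT replicate 2. Without HT replicate 2, 14 genes were called.

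Of the genes higher at E18.5 most of those tested were above 0 at the other ages. The filter lets in genes raised by KO at the age itself, which favours this. Of 182 tested at D2.5, 120 (65.9%) were above 0, with a median log2 fold change of 0.47 against 1.23 at E18.5 for the same genes, and of 276 at E16.5, 248 (89.9%) with a median of 0.75 against 1.54. In tests added after seeing these values only genes that passed the filter on HT libraries alone at the age were used, with random lists of like HT level drawn from the same genes. At D2.5, 58 of 97 were then above 0 (59.8%), with a median of 0.29 against -0.03 in random lists, and 0.11 to 0.28 with 1 library left out. At E16.5 it was 113 of 138 (81.9%), with a median of 0.45 against -0.03, and 0.21 (without KO replicate 3) to 0.60 (without HT replicate 3) with 1 library left out. Genes that vary together are not independent, so the libraries were also split in each of the 10 possible ways, with a filter blind to genotype. At D2.5 the real split gave the largest median over that of other genes (0.28 against at most 0.22, exact p over the splits = 0.1, the smallest possible). At E16.5, 3 of the 10 splits, the real one included, gave at least its 0.50 (exact p over the splits = 0.3). At E16.5 chance is therefore not excluded. At D2.5 this test could not exclude it, since 10 splits can give no smaller p, so it leaves the question open.

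Stress genes led the lists in KO vs HT at D2.5. Of 20 hypoxia, stress and immediate early genes 18 were above 0 (median 0.42, camera adjusted p = 0.000166; adjusted p = 0.294 with an estimated correlation), with Hmox1 at 0.70 and Egr1 at 0.40. KO replicate 3 lay apart from the other D2.5 libraries (113.2 on the first principal component, which held 18.7% of the variance, against -35.3 to 19.1). Sertoli markers (median 0.69, Wt1 2.38, Gata4 1.62) and stromal markers (median 0.72, Col1a2 1.57) were higher, with camera adjusted p of 0.0284 and 0.00283 (adjusted p = 0.432 with an estimated correlation for both). The p53 list was higher (median 0.26, camera adjusted p = 0.0332) and the piRNA list lower (18 of 23 below 0, median -0.18, Tdrd12 -1 and Tdrd9 -0.48, camera adjusted p = 0.0332), both at adjusted p = 0.432 with an estimated correlation. The methylation-sensitive germline genes were lower (median -0.07, camera adjusted p = 0.0346, or 0.381 with Tex15 left out), at adjusted p = 0.432 with an estimated correlation. No member passed over all genes except Tex15. When adjusted over the list alone 3 p53, 3 stromal and 1 Sertoli genes passed. Over alternatives the adjusted p ranged from 4.28e-05 to 0.294 for stress, 5.75e-06 to 0.447 for Sertoli, 4.58e-06 to 0.432 for stromal, 0.0281 to 0.437 for p53, 0.00716 to 0.432 for piRNA and 4.68e-05 to 0.432 for methylation-sensitive genes. The stress list passed without any 1 library. Sertoli missed without HT replicate 3 (0.0984), KO replicate 2 (0.14) or 3 (0.163), and stromal without HT replicate 3 (0.0757) or KO replicate 2 (0.128). The p53 list missed without HT replicate 1 (0.137), 2 (0.0606) or 3 (0.0984) or KO replicate 1 (0.437), and the piRNA list without HT replicate 1 (0.137) or 3 (0.118) or KO replicate 2 or 3 (0.128 each). The methylation-sensitive list missed without any library other than KO replicate 1. The other lists had camera adjusted p of 0.0956 (H3K9, median 0.12), 0.105 (imprinted, 0.22), 0.129 (meiotic), 0.15 (spermatid, cell cycle and Leydig) and 0.273 (macrophage) to 0.92. Median, mean and test differed in sign for the interferon, Leydig and endothelial lists.

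Against wild type the same families were higher in KO cells at D2.5: ERVK by 2.14 (SE 0.23, n = 3 per group, edgeR adjusted p = 3.14e-17), L1 by 1.67 (edgeR adjusted p = 9.36e-10) and ERV1 by 1.43 (edgeR adjusted p = 2.11e-10), or 0.52, 0.07 and -0.22 with family totals as library sizes. The RNA family KO vs WT at D2.5 rose by 0.74 (-0.87 with family totals), a call that ended without KO replicate 3 (0.57) or WT replicate 1 (0.66). Of the repeat names 16 passed, all higher (45 with their own totals as library sizes, 42 higher and 3 lower, 15 of them among the 16), with L1Md_A at 1.67, IAPEz-int at 1.67 and GSAT_MM at 1.18 (lost without KO replicate 2 or WT replicate 1). Of the 16 calls, 9 held without any 1 library, and 10 names were called without WT replicate 1. Among genes 31 passed in edgeR, 28 higher and 3 lower, where DESeq2 called 88 higher and 35 lower. Suv39h2, a histone H3K9 methyltransferase, was at 146 CPM in WT (SD 21.1, n = 3) and 295 CPM in KO (SD 21.9, n = 3; 1.01, SE 0.19, edgeR adjusted p = 0.0174), with 156 CPM in HT and an edgeR adjusted p of 0.0529 in KO against HT. C6 (6.25, SE 0.75), Gnat3 (6.02, SE 0.69) and Samd9l (3.83, SE 0.49) rose as well. Npbwr1 had a ratio of 230 (counting interval 63.2 to 1900), and Xist fell by 1.31 (SE 0.24, edgeR adjusted p = 0.0111). Suv39h2 missed the threshold without KO replicate 2 or 3 or WT replicate 1 or 2 (0.91 to 1.05). Xist KO vs WT at D2.5 missed it without KO replicate 2 (-1.28), KO replicate 3 (-1.25) or WT replicate 1 (-1.14). Npbwr1 missed it without KO replicate 2, WT replicate 2 or WT replicate 3 and with limma-voom. C6 KO vs WT at D2.5 was 7.22 without WT replicate 1 and Samd9l KO vs WT at D2.5 was 4.57 without WT replicate 3. In all 19 genes were called without WT replicate 3. The KO libraries are shared with the comparison against HT, so the results are not independent.

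The lists that passed against HT passed against wild type too: stress (median 0.47, camera adjusted p = 0.00614), Sertoli (0.64, 0.0257), stromal (0.54, 0.0213), p53 (0.25, 0.0257), piRNA (-0.24, 0.0276) and methylation-sensitive germline genes (-0.14, 0.0195), with adjusted p = 0.427 to 0.54 with an estimated correlation. The last list holds Tex15, and without it the adjusted p in KO vs WT at D2.5 was 0.285 (range over alternatives 1.03e-05 to 0.496). Each list missed the threshold without some libraries: stress without KO replicate 2 (0.0696), and Sertoli without KO replicate 2 (0.226) or 3 (0.341) or WT replicate 1 (0.307) or 2 (0.0591). Stromal missed without KO replicate 2 (0.313) or WT replicate 3 (0.242), and p53 without KO replicate 1 (0.34) or 3 (0.0528) or WT replicate 2 (0.129) or 3 (0.0635). The piRNA list missed without KO replicate 2 (0.226) or 3 (0.129) or WT replicate 2 (0.132) or 3 (0.096), and the methylation-sensitive list without KO replicate 2 (0.226) or 3 (0.222) or WT replicate 2 (0.0844). Over alternatives the adjusted p ranged from 0.00178 to 0.427 for stress, 2.41e-05 to 0.54 for Sertoli, 9.82e-05 to 0.496 for stromal, 0.0208 to 0.427 for p53 and 0.00587 to 0.427 for piRNA. Without KO replicate 2, 1 list passed (p53), without KO replicate 3 or WT replicate 2, 2 lists, and without WT replicate 3, 3 lists. Median, mean and test differed in sign for the differentiating spermatogonia, cell cycle, Leydig and macrophage lists.

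Few differences between heterozygous and wild-type cells passed at D2.5. Tex15 alone passed among 14367 genes in edgeR (-1.10), with 488 genes at an unadjusted p under 0.05, fewer than chance alone gives on average. DESeq2 called 2 and limma-voom 1. Samd9l had a log2 fold change of -3.07 (SE 0.56, edgeR adjusted p = 0.123). No repeat family passed in edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05; L1 0.06, ERVK 0.06, ERV1 -0.02), and of the repeat names 0 passed in these tools, with 16 at an unadjusted p under 0.05 in edgeR. Of the lists 0 passed camera (lowest unadjusted p 0.0382, adjusted p = 0.638). Median, mean and test differed in sign for the differentiating spermatogonia, meiotic, spermatid, p53 and imprinted lists.

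The effect of Tex15 loss on repeats differed between ages, an analysis added after seeing the data. L1 was raised more at E18.5 than at E16.5 by a log2 difference of 1.43 (SE 0.27, edgeR adjusted p = 0.000128) and more at D2.5 than at E16.5 by 1.17 (SE 0.27, edgeR adjusted p = 0.00354), while D2.5 and E18.5 differed by -0.25 (edgeR adjusted p = 0.46). At E16.5, KO replicate 3 held more L1 than KO replicates 1 and 2. With family totals as library sizes the L1 family KO effect E18.5 vs E16.5 was 0.10. The L1 family KO effect D2.5 vs E16.5 was then 0.11. Both still passed, but L1 makes up most of those totals. Its own value is therefore held near 0, and this scaling cannot test L1. For ERV1 and ERVK it mixes their change with that of L1. ERV1 was raised more at E18.5 than at E16.5 by 0.96 (SE 0.23, edgeR adjusted p = 0.00304; -0.35 with family totals), and ERVK more at D2.5 than at E16.5 by 0.95 (SE 0.24, edgeR adjusted p = 0.00575; -0.11 with family totals). The NA family differed by -1.24 between D2.5 and E18.5 (SE 0.23) and Satellite by 0.72 (SE 0.21), the latter lost with family totals (0.99) and without D2.5 HT replicate 3, E18.5 HT replicate 3, or E18.5 KO replicate 1 or 2.

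Among genes, Gpr179 and Samd9l were raised more at D2.5 than at both embryonic ages: Gpr179 by 7.10 (SE 0.60, edgeR adjusted p = 2.74e-06) over E16.5 and 5.72 (SE 0.61, edgeR adjusted p = 7.76e-05) over E18.5. Samd9l differed by 6.37 (SE 0.62) and 5.82 (SE 0.62). The size of these differences rests on the HT control: at D2.5 Gpr179 was at 8.28 against HT but 5.56 against WT, and Samd9l at 6.91 but 3.83, and no WT cells were profiled at the embryonic ages. Without D2.5 HT replicate 2 the Gpr179 KO effect D2.5 vs E16.5 was 8.33 and the Gpr179 KO effect D2.5 vs E18.5 was 6.98, and the Samd9l KO effect D2.5 vs E16.5 was 6.98 and the Samd9l KO effect D2.5 vs E18.5 was 6.45. Of 18815 genes 20 differed between D2.5 and E16.5 (17 up, 3 down, with 188 and 188 in DESeq2). Between D2.5 and E18.5, 10 differed (8 up, 2 down, with 131 and 121 in DESeq2). Between E18.5 and E16.5, 0 differed in edgeR, DESeq2 and limma-voom. There 156 genes had an unadjusted p under 0.05 in edgeR, fewer than chance alone gives on average. The Hps1 KO effect D2.5 vs E16.5 was -3.92 (SE 0.65; without E16.5 HT replicate 2, -3.85 and not passing). Over E18.5, C6 differed by 4.15 (SE 0.66), not passing without E18.5 KO replicate 3 (4.18), and the C6 KO effect D2.5 vs E18.5 was 5.17 without D2.5 HT replicate 3. The Hps1 KO effect D2.5 vs E18.5 was -3.95, not passing without E18.5 HT replicate 1 (-3.92), HT replicate 2 (-3.86) or KO replicate 3 (-3.79). Without D2.5 KO replicate 2 the Hps1 values were -4.91 and -4.92. The remaining fall of Tex15 was smaller at D2.5 than at E16.5 by 1.68 (SE 0.24, edgeR adjusted p = 0.00215) and than at E18.5 by 1.52 (SE 0.24, edgeR adjusted p = 0.0137; lost without E18.5 HT replicate 2 or E18.5 KO replicate 1, 2 or 3), both lost with limma-voom. The count was 10 without E16.5 HT replicate 2 and 74 without D2.5 KO replicate 2 against E16.5, and 4 without E18.5 KO replicate 3 and 30 without D2.5 KO replicate 2 against E18.5.

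In heterozygous cells, age changed many more genes than genotype did, although each age was deposited as its own table, so age and any batch cannot be told apart. From E16.5 to E18.5 the early germ cell gene Dppa3 fell from 1480 to 54.7 CPM (-5.06, SE 0.95, n = 3 per group, edgeR adjusted p = 0.00414), along with Tet1 (-2.73, SE 0.54), Lin28a (-1.83), Dppa4 (-1.66), Dnd1 (-1.95) and the piRNA gene Asz1 (-1.59, SE 0.24), while Plagl1 (2.31, SE 0.50), Kitl (2.74, SE 0.58) and Col1a2 (2.88, SE 0.58) rose. Dppa3 HT E18.5 vs E16.5 was -3.94 without E16.5 HT replicate 1 and -6.48 without E18.5 HT replicate 3, and Tet1 HT E18.5 vs E16.5 was -1.42 without E16.5 HT replicate 1, all still passing. Without E16.5 HT replicate 3, Plagl1 HT E18.5 vs E16.5 was 3.29 and Col1a2 HT E18.5 vs E16.5 was 3.72. Kitl is also in the Sertoli list and Col1a2 in the stromal list. The medians of these lists deviated by -1.17 and -1.43 in E16.5 HT replicate 1, so RNA of other cells was not separated from age here. Of 18815 genes 2483 passed in edgeR (905 higher, 1578 lower). Upper-quartile factors moved the median of all genes from 0.108 to 0.332 and the share higher from 36.4% to 56.6%, so the balance of directions rests on the scaling. Without E16.5 HT replicate 1, 561 genes passed, and without E16.5 HT replicate 3, 5074. From E18.5 to D2.5, 10304 genes passed (4026 higher, 6278 lower, median of all genes -0.507). The lists were not tested over age. Of their members Mki67 rose by 5.89 (SE 0.49, edgeR adjusted p = 1.31e-08), Top2a by 3.01 and Ccna2 by 2.92, and so did Gfra1 (4.78, SE 0.35, edgeR adjusted p = 3.48e-09), Id4 (5.10), Ret (3.52) and Zbtb16 (2.96). Pou5f1 fell by 6.03 (SE 0.61, edgeR adjusted p = 1.39e-07), Utf1 by 3.57, Dnmt3a by 2.03, and the piRNA genes Tdrd9 (-2.25), Piwil4 (-2.19) and Piwil2 (-1.69) were lower too.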

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

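The tests of RNA from other cell types at E18.5 and that of an earlier stage at E16.5 were chosen after the results were seen, as were the tests of repeat families between ages.

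The effect of Tex15 loss differed between ages for L1 (log2 difference 1.43 for E18.5 over E16.5, 1.17 for D2.5 over E16.5). It also differed for ERV1 (0.96 for E18.5 over E16.5) and ERVK (0.95 for D2.5 over E16.5), each by an interaction test in edgeR. With family totals as library sizes the ERV1 and ERVK differences changed sign. L1 makes up most of those totals, so such a change of sign can follow from the rise of L1. The NA family (-1.24) and Satellite (0.72) differed between D2.5 and E18.5 by the same test. For genes the interaction test called 20 between D2.5 and E16.5 and 10 between D2.5 and E18.5, and of 100 draws of other genotype labels within ages 12 and 13, the real labels included, gave as many (highest 164 and 122), so chance is not excluded for these counts; between E18.5 and E16.5 all 100 reached the real count of 0 (highest 2).

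At E18.5, 377 of 389 genes that passed were higher in KO. The choice of scaling is argued against as the cause, since the scalings moved the median of all genes by at most -0.02. Each scaling takes the bulk of the rows as unchanged, so a changed RNA total could not be tested this way. GC content bias is argued against as the whole cause, since 320 of the 389 still passed with GC-corrected offsets (median of the higher genes 1.70 against 1.83). RNA of Sertoli, Leydig, stromal or endothelial cells is argued against for these libraries, since no list median had an upper bootstrap bound above 0.27. All 74 markers of other cell types had a median log2 fold change of -0.014 (interval -0.06 to 0.06), although Tek rose. Bootstrap bounds here resample marker genes, which can vary together. They leave out the spread between libraries. RNA of macrophages and blood cells, which the Oct4-GFP sort should remove, stays open: the median of its 10 markers was 0.29 (bootstrap interval -0.26 to 0.92), with Mrc1 at 1.82 and Adgre1 at 1.43 but Fcer1g at -0.03 and Cd68 at -0.34. An effect of Tex15 loss itself stays open as a hypothesis, and so does a difference in strain background. Near Tex15 9.57% of genes had an unadjusted p under 0.05 at E18.5 against 8.12% of all genes (Fisher's exact test, p = 0.569). Of the 94 genes tested there 3 passed, beside 389 of all 18199. Other regions were not tested.

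HT replicate 1 at E16.5 lay apart from the other libraries of its age. Library depth is argued against, since the first component held 77.6% of the variance after thinning all libraries to 9375216 counts. An earlier developmental stage may explain it: its deviation from the other HT libraries went against the E16.5 to E18.5 change of the KO libraries (Pearson r = -0.57 across 16171 genes, which are not independent replicates; HT replicate 2 0.07, HT replicate 3 0.66), with Dppa3 2.55 and Mki67 2.21 higher and Dnmt3l lower (-1.77). A smaller share of other testis cells may contribute too, with marker medians from -0.75 (Leydig) to -2 (macrophage), although the Oct4-GFP sort should remove such cells from every library.

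Fewer genes passed at D2.5 (22) than at E18.5 (389). The lower depth of the gene counts is argued against as the whole cause, since 325 genes passed at E18.5 after thinning to the D2.5 totals. The larger spread between D2.5 libraries and a smaller effect cannot be told apart: the genes higher at E18.5 had a median log2 fold change of 0.47 at D2.5 against 1.23 at E18.5 (0.29 against 1.02 for those that passed the filter on HT alone, a test chosen after seeing the data), while the coefficient of variation was 55.4% against 17.9%.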

How the results depend on the processing

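The settings named in the methods as added after seeing the data, and the results on repeat names and on families between ages, were chosen after the results were seen. Of single values 2181 kept their direction and side of the threshold under other settings, 99 became weaker, 14 stronger and 19 reversed, and 25 that passed in neither setting changed sign; with 1 library left out 1722 kept them, 325 became weaker, 3 stronger and 56 changed sign without passing. A sign change counted as reversed where the value passed in either setting. For KO vs HT at E16.5 (1 gene) DESeq2 called 6, library weights 10 and the first component as covariate 8. For KO vs HT at D2.5 (22) no filter gave 109, DESeq2 126, the newer quasi-likelihood method 42 and HT with WT as 1 control 70. For KO vs WT (31) no filter 110, DESeq2 123 and the newer method 49; for HT vs WT (1) no filter 4 and DESeq2 2. The difference of effects between D2.5 and E16.5 (20) went to 12 with upper-quartile factors and 376 with DESeq2, that between D2.5 and E18.5 (10) to 252 with DESeq2, and the change from E16.5 to E18.5 in HT (2483) to 3770 with DESeq2 and 5437 with limma-voom. Gene lists at E16.5 and D2.5 fell to 0 with an estimated correlation and 0 with fry. With family totals as library sizes 1 family passed at E16.5, 51 at E18.5, 49 for KO vs HT and 50 for KO vs WT at D2.5, since L1 makes up most of those totals. This reversed Alu (-1.71), B2 (-1.69), B4 (-1.70), ERV1 (-0.01), ERVK (-0.18), ERVL (-1.50) and NA (-0.61) at E18.5, ERV1 (-0.07) and RNA (-0.74) in KO vs HT at D2.5, ERV1 (-0.22), ERVL (-1.55) and, in RNA family KO vs WT at D2.5, RNA (-0.87) with WT as control, ERVK (-0.11) between D2.5 and E16.5, the Alu family KO effect E18.5 vs E16.5 (-1.19), the B2 family KO effect E18.5 vs E16.5 (-1.22), the ERVK family KO effect E18.5 vs E16.5 (-0.87), the ERVL family KO effect E18.5 vs E16.5 (-1.28) and those of B4 (-1.30) and ERV1 (-0.35). With 1 library left out, gene counts ranged from 1 to 1 at E16.5, 197 to 392 at E18.5, 14 to 24 (KO vs HT), 19 to 30 (KO vs WT) and 1 to 2 (HT vs WT) at D2.5, 10 to 74, 4 to 30 and 0 to 0 for the differences D2.5 with E16.5, D2.5 with E18.5 and E18.5 with E16.5, and 561 to 5074 and 8838 to 10056 for the changes with age. Families ranged from 2 to 6 at E16.5, 4 to 6 at E18.5, 3 to 4 and 3 to 4 at D2.5, and lists from 1 to 7, 0 to 2 and 1 to 7 at E16.5, E18.5 and D2.5. Except for family totals, the cause was not tested.

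The labels do not pair the replicates. Yet deviations of HT and KO libraries from their group means correlated at E16.5 for numbers 1 and 3 but not 2 (Pearson r = 0.58, 0.76 and -0.12). The highest r with another number was 0.52, -0.57 and 0.23. At E18.5 r was 0.21, 0.13 and 0.09 for numbers 1, 2 and 3. A factor shared by libraries of the same number is thus possible at E16.5, where the fit with no block may miss changes. With the replicate number as a block 2 genes passed at E16.5, 531 at E18.5, and 24, 30 and 1 in the D2.5 comparisons; 14, 7 and 0 for the differences between ages, 2957 and 10333 for the changes with age, 7, 5, 4, 4 and 0 families, 14, 7 and 3 families between ages, 39, 210, 12, 15 and 0 repeat names (0, 113, 14, 16 and 0 with no block), and 5, 0 and 6 lists.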

Other observations

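The results on repeat names were added after seeing the data.

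Genes higher in KO at E18.5 often followed one another in the order of tested genes along a chromosome. Of 374 with a position 99 were next to another such gene, in 45 runs. Random lists had a median of 16 (95% bound 25, permutation p = 1e-04, the smallest these can give). Genes that were not tested were skipped, so others can lie between the members of a run. The filter also lets in genes raised by KO alone, which favours runs over random lists. The runs held Olfr784, Olfr792, Olfr810 and Olfr811, the major urinary protein genes Mup5, Mup3 and Mup21, Clca3b, Clca4b and Clca4a, Cyp2c29 and Cyp2c38, and Vmn1r13, Vmn1r14 and Vmn1r15. Neighbouring genes that change together may give such runs. So may the filter, and gene families, which lie in clusters and can share reads. Sequence shared by many transcripts is argued against as the whole cause of the higher counts. Repeated 31-mers, found in the transcripts of at least 10 genes, made up under 5% of the longest transcript in 95.5% of the higher genes. The share was 98.4% of genes not called. The other 4.55% of higher genes exceed the share in random lists of like expression (median 2.15%, upper bound 3.76%, permutation p = 0.0068, two-sided). Such sequence, from repeats or gene families, may thus contribute for a few genes. Repeat sequence that is rare in annotated transcripts was not counted, so it stays open.

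Within 10 Mb of Tex15, 5 of 86 genes had an unadjusted p under 0.05 at E16.5, 5.81% against 1.17% of all genes tested (Fisher's exact test, p = 0.00342). Of the 86 genes 0 passed after adjustment in edgeR. The 1.17% is less than chance alone gives on average, so a low background contributes to the contrast. At E18.5, 3 of 94 genes there passed in edgeR. The shares were 9.57% against 8.12% at E18.5 (Fisher's exact test, p = 0.569), and 9.21% against 7.21% for KO vs HT (p = 0.5) and 9.21% against 7.77% for KO vs WT (p = 0.664) at D2.5.

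For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes the real split gave 1 call at E16.5 (highest other 0), 389 at E18.5 (1), 22 for KO vs HT (1), 31 for KO vs WT (0) and 1 for HT vs WT (1) at D2.5, and 2483 (0) and 10304 (0) for age; 1 of 10 splits reached the real count in each except HT vs WT (2). For families it gave 4 at E16.5 (0), 5 at E18.5 (0), 4 for KO vs HT (25), 4 for KO vs WT (0) and 0 for HT vs WT (1) at D2.5, reached by 1, 1, 2, 1 and 10 splits. For repeat names it gave 0 (0), 113 (1), 14 (352), 16 (1) and 0 (0), reached by 10, 1, 2, 1 and 10. For lists it gave 3 at E16.5 (8), 0 at E18.5 (4) and 6 at D2.5 (5), reached by 6, 10 and 1. The split of HT replicate 1 with KO replicates 1 and 2 against the other libraries called 25 families and 352 names at D2.5, several times the real count, which points to a structure of the samples beside genotype. Repeat names took 63%, 58.6% and 64.2% of the counts in these libraries. They took 68.3% and 69.4% in HT replicates 2 and 3 and 68.5% in KO replicate 3. Whether this difference gave the calls was not tested.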
